A study of Arabidopsis thaliana with 12 samples.

How the data were processed

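Total RNA of 12 samples of Arabidopsis thaliana, 6 control and 6 recovered, was measured on arrays of 3439 probes. The deposited table holds one intensity per probe and sample on a linear scale from 0 to 100, and how the authors corrected, scaled and floored these intensities is not given in the sources used here. The values themselves show that the arrays had not been quantile normalized, that 4 probes stood at the ceiling of 100 on all recovered arrays and none on all control arrays, that 6 probes stood there on any array, and that 8.89% of all values were exactly 0. The array platform, the light intensity, the plant tissue and the origin of the replicates are likewise not given in the sources used here. The scale and any background subtraction therefore stay unknown, and the intensities are in arbitrary units.

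Samples were grouped by the growth and recovery conditions in the labels. The comparison was recovered against control plants, without a replicate block, and a log2 difference is recovered minus control. Because more than 5% of values were 0, the 1030 probes with a value of 0 on any array were left out, which left 2409 probes, and because column totals differed by more than 5% the log2 intensities were quantile normalized. Recovered arrays held more zeros than control arrays (454.2 ± 82.7 against 157.5 ± 2.95), so this filter was not blind to the group. Each probe was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 2409 probes and a threshold of 0.05 on the adjusted p. Means ± SD in the text are of deposited intensities, and log2 differences, their SE and adjusted p are of quantile-normalized values unless another scaling is named. Group differences in totals, medians, 99th percentiles and zeros were tested with exact two-sided permutation tests. The number of arrays limits the precision.

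The platform annotation used here names a single gene for 692 probes, several genes for 870 and none for 1877, and no gene is named from a probe with several. Of the 692 single-gene identifiers 690 matched the TAIR10.1 gene table, from which symbols were taken, and 468 of these probes were tested. The single-gene probes named 691 genes, and 1 of them, AT2G25870, had more than 1 probe. Genes named in the text were set by a rule: the 10 single-gene probes with the largest log2 increase and the 10 with the largest decrease past the threshold, up to 2 members of each of 18 gene lists with the smallest p, and ELIP1, ELIP2, COR15A, COR15B, PSBS, HSP21, RBCS1A, LHCB1.1, PORC, CHS, RD29A, FTSH8, SAPX and GPT2 irrespective of result. None of the last group had a tested probe that names it alone, and these genes are not analysed here. PSBW, PRPL17 and PRPL5 were named beyond the rule so that all 15 tested list members appear.

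Consecutive samples of a group (1 and 2, 3 and 4, 5 and 6) were checked for likeness. In control samples the deviations of log2 intensity from the group mean, across the 2409 probes, correlated at 0.813 to 0.927 within such pairs and at -0.665 to -0.112 otherwise; probes are not independent replicates. In recovered samples the same correlations were -0.115 to 0.00921 within pairs and -0.279 to -0.187 otherwise. Results with consecutive samples averaged, giving 3 values a group, are therefore printed beside the main counts and the called genes named in the report; no label states that these samples are technical pairs.

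The test was tested on simulated data with the 2409 probes and 50 probes changed at each log2 fold. With 12 independent samples it recovered 24%, 68%, 98% and 100% of probes changed by a log2 fold of 0.5, 1, 2 and 4, and 2.03% of its calls were false. Samples were also drawn as correlated pairs (correlation 0.624, as estimated by limma's duplicateCorrelation). Then 35.8% of the calls of the 12-sample fit were false, against 6.67% after averaging pairs. Averaging recovered 6%, 38%, 86% and 94% of probes changed by these log2 folds. In the data 1653 of 2409 probes were called, far more than were changed here, and the share of false calls depends on that number. Both groups were given the same likeness within pairs, which recovered samples showed less than control samples. The choice of scaling was not simulated. These shares therefore do not carry over to the data.

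Alternatives covered other scalings (as deposited, median centring, cyclic loess), filters on dim probes, an offset, array weights, a robust variance model, an exact permutation test per probe, the replicate number as a block, averaging of pairs, the handling of zeros, stricter thresholds, and leaving out each sample or pair. Plots were drawn with matplotlib.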

Results

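Transcript levels were measured in wild-type Arabidopsis thaliana of the ecotype Columbia 0 by hybridizing total RNA to expression arrays. Of the 12 arrays, 6 carried RNA of control plants kept in medium light at 20 °C. The other 6 carried RNA of recovered plants, which had spent 24 h at 4 °C in medium light, a treatment that the labels describe as photoinhibitory, and then another 24 h back at 20 °C in the same light. Each array held one value for each of 3439 probes, and the spot intensities of an array summed to 3679 ± 39.7 in control and 3214 ± 39.9 in recovered samples (SD, n = 6 each). The median spot differed more, at 0.556 ± 0.0159 in control and 0.108 ± 0.0142 in recovered samples, which is 5.14 times lower after recovery (exact two-sided permutation p = 0.00216, the smallest that 6 against 6 samples can give). The brightest spots differed in the opposite direction, with a 99th percentile of 8.65 ± 0.200 in control and 12.7 ± 0.412 in recovered samples (exact permutation p = 0.00216). The number of spots listed at 0 was 157.5 ± 2.95 in control and 454.2 ± 82.7 in recovered samples (exact permutation p = 0.00216). No source used here says whether the samples of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Consecutive recovered samples held near-equal numbers of zeros (416 and 409, 564 and 556, 388 and 392). The permutation tests may therefore count 6 samples a group where fewer are independent.

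**Figure D1:**
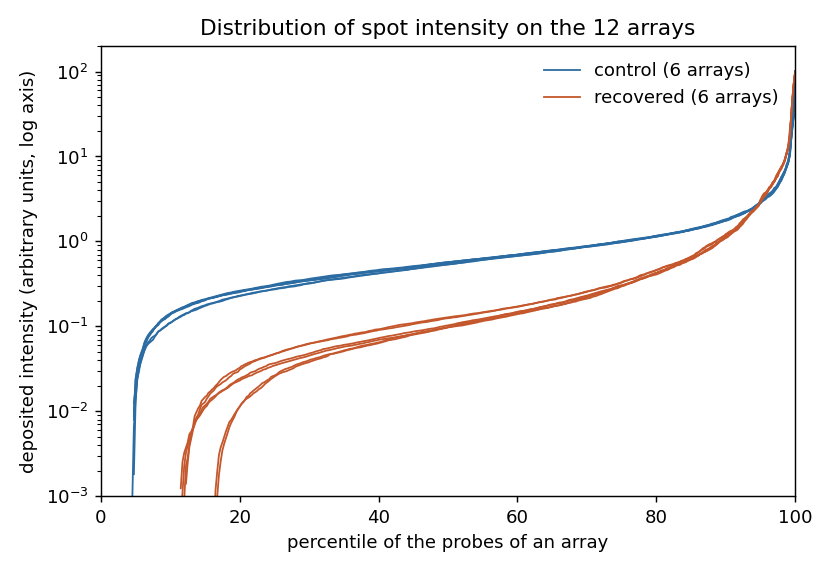
Spot intensity (arbitrary units, log axis) at each percentile of the probes of an array, with one line per array for the 6 control and 6 recovered samples. Control medians lie between 0.536 and 0.569 and recovered medians between 0.0971 and 0.128, while the curves cross near the bright end.

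The comparison asks which transcripts differed from the control level after 24 h of recovery from the cold. No sample of the series was taken at the end of the cold. A difference that lasted from the cold and one that arose during recovery therefore cannot be told apart. AT3G52960, the plastid type II peroxiredoxin PRXIIE that reduces peroxides, fell from an intensity of 2.93 ± 0.536 in control to 0.147 ± 0.0504 in recovered plants (SD, n = 6 each), a log2 difference of -3.38 (SE 0.203, adjusted p = 3.46e-08). AT4G18180 fell from 4.22 ± 0.461 to 0.0710 ± 0.0354, a log2 difference of -5.04 (SE 0.193, adjusted p = 1.35e-09), and AT4G35660 fell from 13.9 ± 2.63 to 0.369 ± 0.101, a log2 difference of -4.91 (SE 0.148, adjusted p = 1.40e-10). PSBY, a small subunit of photosystem II, rose from 1.55 ± 0.201 to 2.86 ± 0.490, a log2 difference of 1.26 (SE 0.146, adjusted p = 8.40e-06). These 4 genes were called in the same direction in deposited, quantile-normalized, median-centred and cyclic-loess values, and also when consecutive samples of a group were averaged first. The sizes depended on the scaling. PSBY was at 0.88 as deposited, 2.81 after median centring and 0.79 after cyclic loess, and PRXIIE at -4.36, -2.43 and -3.21.

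After quantile normalization, limma called 1653 of 2409 tested probes at an adjusted p under 0.05, 903 higher and 750 lower after recovery. Among the 468 tested probes that name a single gene, 166 were higher and 156 lower, or 127 and 118 with consecutive samples averaged. The direction of many calls rested on the scaling: in the deposited values, with no further normalization, 238 probes were higher and 1819 lower, so the share of higher calls was 11.6% against 54.6% after quantile normalization. Called the same way in all 4 scalings were 189 probes higher and 534 lower. Of these 18 and 110 name a single gene, and 173 and 479 also passed with consecutive samples averaged. Median centring adds the same amount to every deposited difference, so these are not 4 separate checks. A higher call had to lie above 0 as deposited, and a lower call below 0 after centring. The median probe lay nearer the second limit (-1.58 as deposited, 0.35 after centring). The balance of 189 against 534 thus depends partly on the scalings chosen. Consecutive samples of the control group resembled each other far more than other control samples did, and averaging consecutive samples of both groups left 693 probes higher and 568 lower.

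**Figure D2:**
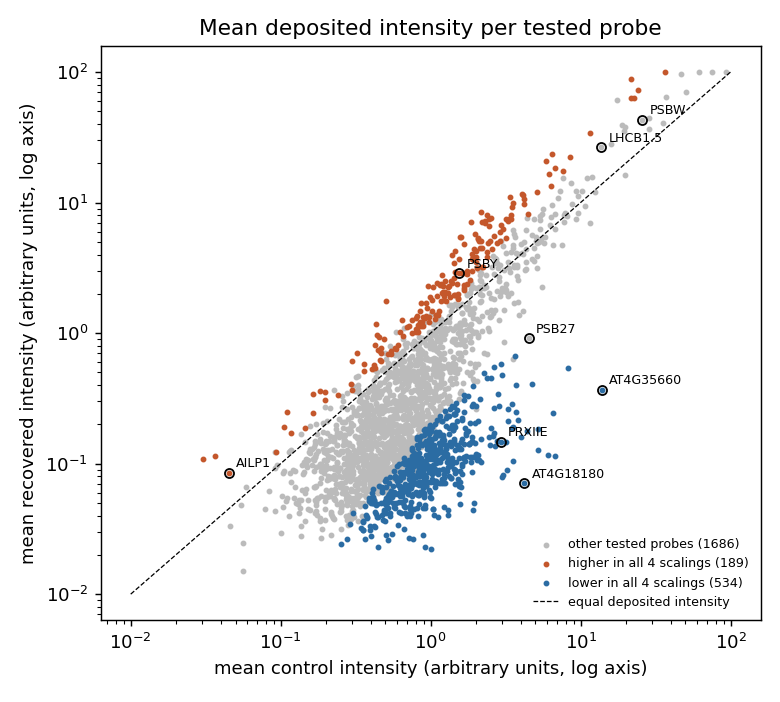
Mean recovered against mean control intensity of the 2409 tested probes (arbitrary units, both axes log), with 189 probes called higher and 534 called lower in all 4 scalings coloured, and the dashed line marking equal deposited intensity. PSBY lies above the line and PRXIIE, AT4G18180 and AT4G35660 lie far below it.

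The 10 single-gene probes with the largest decreases had log2 differences from -2.94 to -5.04, and all 10 were called lower in each of the 4 scalings and with consecutive samples averaged (adjusted p at most 0.00646). Control means of these genes ranged from 0.9995 to 13.9 and recovered means from 0.0223 to 0.369. The background is unknown, so the sizes of these decreases are uncertain. Besides PRXIIE, AT4G18180 and AT4G35660, they were AT3G18870 (log2 difference -4.45), AT2G31920 (-3.65), PRA1.B6, a member of the prenylated Rab acceptor family of membrane proteins (-3.55), AT5G15390 (-3.38, or -2.58 without recovered sample 4), AT1G73740 (-3.36), AT1G31790 (-3.35) and AT3G50270 (-2.94).

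The 10 single-gene probes with the largest increases after quantile normalization were dim, with control means from 0.0451 to 0.174, below the 25th percentile of every control array (0.272 to 0.311). Deposited intensities of the groups did not overlap for 0 of these 10, against 10 of the 10 largest decreases. Both sets were chosen from the same arrays, and deposited values were lower after recovery for most probes (median log2 difference -1.58). This contrast is therefore partly built in, and the share over all probes was not counted. AILP1, an aluminium-induced protein, rose from 0.0451 ± 0.00689 to 0.0852 ± 0.0297 (SD, n = 6 each), a log2 difference of 4.19 (SE 0.285, adjusted p = 8.64e-08). It was higher in deposited values by only 0.83 on the log2 scale (adjusted p = 0.00788). Recovered sample 2, at 0.0383, lay below every control sample (0.0394 to 0.0579). The other 9 did not pass the test in deposited values (adjusted p from 0.114 to 0.978), where 6 of them had a difference below 0. Their increases are thus relative to the other probes of the array. They were AT1G42960 (log2 difference 3.47), AT4G16060 (3.01), AT1G62780 (2.94), AT2G34450 (2.90), AT4G05030 (2.62), AT1G64510, the plastid ribosomal protein PRPS6 (2.61), UGT74D1, a UDP-glucosyltransferase (2.40), IQD22, a calmodulin-binding IQ-domain protein (2.38), and CBL, the cystathionine beta-lyase of methionine synthesis (2.303). All 10 also passed with consecutive samples averaged (adjusted p at most 0.0115), while IQD22 missed the threshold after median centring (adjusted p = 0.05003) and after cyclic loess (adjusted p = 0.0607).

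Of the 361 members of 18 gene lists, 15 had a tested probe that names them alone, and of these 6 were higher, 2 were lower and 7 did not pass, with 6 higher and 2 lower when adjusted over the list alone. With consecutive samples averaged 5 passed. In deposited values 4 were higher and 8 lower. Among 3 subunits of photosystem II, PSBY rose, PSB27 was called lower and PSBW did not pass. PSB27, a lumenal protein of photosystem II assembly and repair, had intensities of 4.53 ± 2.67 in control and 0.918 ± 0.214 in recovered plants (log2 difference -1.56, SE 0.598, adjusted p = 0.0342). Control samples 1 and 2 lay at 1.2997 and 1.19 and the other 4 between 5.02 and 7.30. The call was lost with consecutive samples averaged (adjusted p = 0.142) and after median centring (log2 difference -0.07, adjusted p = 0.893). It held as deposited (log2 difference -1.999, adjusted p = 0.00155) and after cyclic loess (-1.98, adjusted p = 0.00270). PSBW had the brightest of these probes, at 25.7 ± 1.74 in control and 43.1 ± 3.73 in recovered plants, with a log2 difference of -0.20 after quantile normalization (adjusted p = 0.102) and 0.74 as deposited (adjusted p = 8.56e-06).

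For photosystem I, the single measured subunit PSAN rose from 3.52 ± 0.457 to 6.14 ± 1.17, a log2 difference of 0.47 (SE 0.154, adjusted p = 0.0173). PSAN did not pass after cyclic loess (log2 difference 0.27, adjusted p = 0.119) or with consecutive samples averaged (adjusted p = 0.123). For the light-harvesting antenna, the single measured member LHCB1.5, a chlorophyll a/b-binding protein of photosystem II, had intensities of 13.7 ± 2.79 and 26.5 ± 3.18, with a log2 difference of -0.05 (adjusted p = 0.762) after quantile normalization and 0.96 (adjusted p = 3.95e-05) as deposited. In the Calvin cycle, 1 of 2 measured members was higher. The phosphoribulokinase PRK had deposited intensities of 0.765 ± 0.193 and 0.766 ± 0.0665, and its log2 difference of 1.39 (adjusted p = 2.84e-05) after quantile normalization became 0.04 (adjusted p = 0.831) as deposited. With consecutive samples averaged PRK passed (adjusted p = 0.00487). The sedoheptulose bisphosphatase SBPASE had intensities of 1.06 ± 0.0622 and 0.419 ± 0.0487, with log2 differences of 0.04 (adjusted p = 0.774) and -1.34 (adjusted p = 1.01e-07) in the same order of scalings.

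Among 4 tested plastid ribosomal proteins, PRPS6 and PRPS10 were higher after quantile normalization, and none was higher as deposited, where 3 were lower. PRPS10 had a log2 difference of 1.45 (adjusted p = 2.16e-06) after quantile normalization and -0.50 (adjusted p = 0.0175) as deposited. It passed with consecutive samples averaged (adjusted p = 0.00183). PRPL17 (-0.19, adjusted p = 0.320) and PRPL5 (0.25, adjusted p = 0.209) did not pass. Another member, PRPL34, was left out of the test because it was listed at 0 on all 6 recovered arrays, against 0.275 ± 0.106 on the control arrays, and PRPL29 was listed at 0 on all 6 control arrays and on 5 recovered arrays. In tetrapyrrole metabolism neither measured member passed after quantile normalization. The geranylgeranyl reductase CHLP had a log2 difference of 0.11 (adjusted p = 0.372), which was 2.04 (adjusted p = 6.97e-09) after median centring. The magnesium protoporphyrin methyltransferase CHLM had one of 0.12 (adjusted p = 0.432), which as deposited was -1.61 (adjusted p = 1.59e-07). The plastid chaperonin subunit CPN60B3 was called higher (log2 difference 0.56, adjusted p = 0.0464), but it lay at -1.62 as deposited (adjusted p = 7.10e-05) and did not pass after median centring (adjusted p = 0.299) or with consecutive samples averaged (adjusted p = 0.0923). PRXIIE was the single measured antioxidant enzyme.

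**Figure D3:**
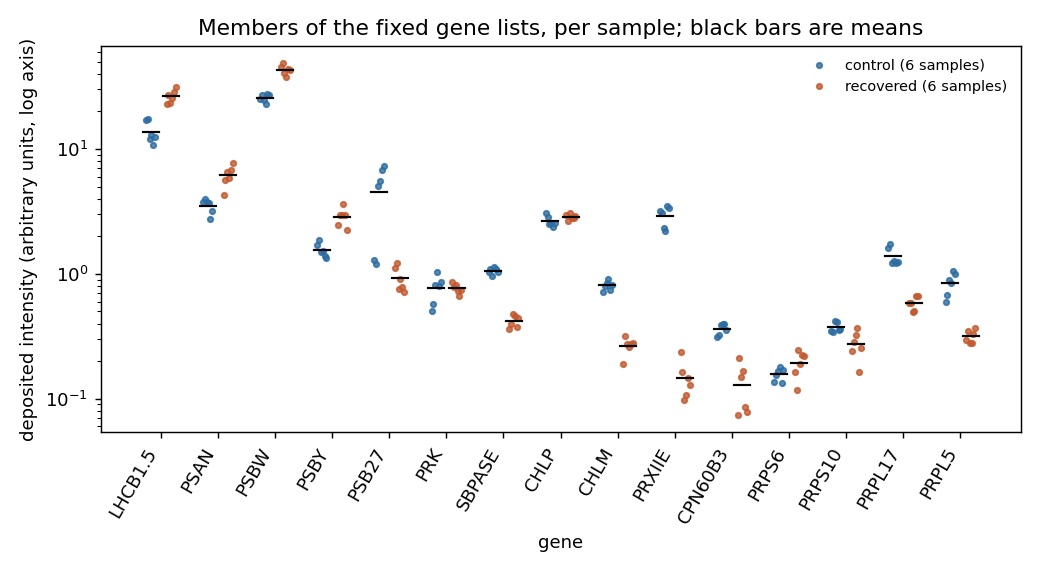
Deposited intensity (arbitrary units, log axis) of the 15 tested list members in each of the 6 control and 6 recovered samples, with black bars at the group means. PSBY lies between 1.34 and 1.87 in control and between 2.22 and 3.63 in recovered samples, PRXIIE between 2.19 and 3.47 and between 0.0980 and 0.238, and PSB27 spreads from 1.19 to 7.30 in control.

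The other 10 lists had no tested member: electron transport and ATP synthase, photoprotection and photosystem II repair, cold-responsive genes, isoprenoid and carotenoid synthesis, starch metabolism and sugar export, photorespiration and nitrogen assimilation, shikimate pathway and phenylpropanoids, plastid protein import, plastid lipids and jasmonate synthesis, and markers of other organs and senescence. No list had 5 tested members, so no test of a list as a set was run. Whether the groups were hybridized in separate batches is not given in the sources used here, and a batch that followed the groups cannot be told apart from them.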

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

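No test in this part was chosen after the result was seen. Among 74 groups of 6 samples checked for a single distant sample, 3 held one, where chance gives about 3.7 if samples are independent. The likeness of consecutive samples puts that in doubt. The check also cannot flag a pair of samples that lie apart together, such as control 1 and 2 for PSB27. For AT2G34450, recovered sample 3 had an intensity of 0.0799, and the other recovered samples lay between 0.145 and 0.185. For IQD22, recovered sample 2 had an intensity of 0.163, and the others lay between 0.0123 and 0.0639. For CBL, recovered sample 4 had an intensity of 0.305, and the others lay between 0.105 and 0.171. All 3 are dim probes among the 10 largest increases.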

How the results depend on the processing

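Chosen only after the data were seen were the constant added to the recovered arrays, the 2 settings that keep probes with zeros, the ceiling filter, the agreement of 4 scalings, and leaving out pairs of samples; the main test, the gene lists, the rule for naming and the other alternatives were fixed before the data were examined. The scaling sets the direction of many calls: the median log2 difference over the 2409 probes was 0.08 after quantile normalization, -1.58 as deposited, 0.35 after median centring and -0.07 after cyclic loess. As deposited, 238 probes were higher and 1819 lower, 203 and 717 of them shared with the main calls and 439 called in the opposite direction. Median centring called 1085 higher and 669 lower, with 91 opposite calls, and cyclic loess 761 and 775, with 1 opposite. Called the same way in 4 scalings were 723 probes, 189 higher and 534 lower. Without the dimmer 50% of probes 947 were called, 532 higher and 415 lower, since fewer were tested, and 1030 changed at least 2-fold, 538 higher and 492 lower. Keeping probes with zeros gave 2212 calls with zeros at the smallest positive value and 2371 with 0.1 added. Leaving out 1 sample gave 1578 to 1637 calls, 873 to 896 higher and 700 to 745 lower, and leaving out 1 pair gave 1548 to 1627, 850 to 889 higher and 687 to 740 lower. Averaging pairs gave 1261 calls, and pairs as a random block 1327. The unknown background limits every dim probe.

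Samples with the same number in both groups were not treated as pairs: their deviations correlated at -0.0256 to 0.102, and 5 of the 12 samples correlated best with their own number, where chance gives 2. Whether they share a slide is not given in the sources used here. With the replicate block 878 probes were higher and 746 lower, of which 862 and 721 were shared with the main calls and 0 opposite, and 1 list member was lower. PSB27 (adjusted p = 0.0581) and PSAN (adjusted p = 0.0567) did not pass with the replicate block, which changed no other named call. The replicate block with median centring gave 11 list members higher and 1 lower.

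Against 8 list members called (6 higher, 2 lower), deposited values gave 8 lower, median centring 11 higher and 1 lower, cyclic loess 4 lower, the filter on 50% of probes 5 called and 3 higher, the exact permutation test 1 lower, averaged pairs 5 called and 1 lower, zeros at the smallest positive value 1 lower, and the added constant 14 called and 5 lower. Leaving out 1 sample or 1 pair gave 6 to 8 called, 5 to 6 higher and 1 to 2 lower. The member lost among lower calls was PSB27, whose log2 difference ran from -2.03 to -1.34 without 1 sample and from -2.71 to -0.99 without 1 pair. PSB27 missed the threshold without control 3, 4, 5 or 6 or recovered 3, 5 or 6, and CPN60B3 missed it in 9 of the 12 cases, all but recovered 1, 5 and 6. CPN60B3 also missed it with median centring (adjusted p = 0.299), the robust variance model (0.0560), the exact permutation test (0.0733), pairs as a random block (0.243) and samples 1 to 3 against 4 to 6 as a batch (0.0563). PSAN missed it with cyclic loess (adjusted p = 0.119) and pairs as a random block (0.0612).

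As deposited, log2 differences changed sign for AT1G42960 (-0.13), AT1G62780 (-0.0059), AT4G05030 (-0.10), UGT74D1 (-0.45), IQD22 (-0.87), CBL (-0.030), PRPS10 (-0.50) and CPN60B3 (-1.62), and, among genes that did not pass in the main test, for SBPASE (-1.34), PRPL5 (-1.39), CHLM (-1.61), PSBW (0.74) and LHCB1.5 (0.96). All other sign changes were among genes that did not pass. With median centring, with or without the replicate block, these were PSBW (2.67), LHCB1.5 (2.89) and PRPL17 (0.69). With cyclic loess they were CHLP (-0.15), LHCB1.5 (0.089), SBPASE (-0.24) and CHLM (-0.024), and with array weights LHCB1.5 (0.11). With the added constant they were PSBW (0.76), LHCB1.5 (0.99), SBPASE (-0.29), PRPL5 (-0.11) and CHLM (-0.18). Without control 1 and 2, LHCB1.5 was at 0.15 and PRPL17 at 0.051. Leaving out 1 sample or 1 pair, LHCB1.5 ran from -0.18 to 0.15, PRPL17 from -0.34 to 0.051 and SBPASE from -0.036 to 0.11. Calls gained included CHLP with median centring (2.04), the added constant (0.32) and without control 1 and 2 (0.23), and PRPL5 (0.54) and SBPASE (0.59) with median centring. PRPL17 passed as deposited (-1.24), with cyclic loess (-0.54) and with the added constant (-0.41). PSBW passed with cyclic loess (-0.25), array weights (-0.24) and the robust variance model (-0.20). AT5G15390 was at -2.58 without recovered 4 and at -2.37 without recovered 3 and 4. Leaving out that pair moved PRA1.B6 to -2.56 and AT1G73740 to -2.53, and leaving out recovered 5 and 6 moved AT1G31790 to -2.67. Among increases, AT2G34450 was at 2.05 without control 1 and 2 and at 3.53 without control 3 and 4. Without control 1 and 2 AT1G42960 was at 4.06 and AT1G62780 at 3.56, and without control 5 and 6 AT4G16060 was at 3.71. Beyond the scalings themselves, the cause was not tested. The alternative that leaves out probes with zeros is the main setting, and the 2 set-test alternatives were not run, as no list had 5 tested members.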

Other observations

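Chosen only after the result was seen were the tests of one scaling factor, of fewer transcripts and of a shared hybridization, as well as the choice of the genes named here. Of the 18 single-gene probes higher in all 4 scalings, 17 also passed with consecutive samples averaged, the exception being AT1G49850 (adjusted p = 0.114). CYN, the cyanase that breaks down cyanate, rose from 2.18 ± 0.0775 in control to 5.03 ± 0.753 in recovered plants (SD, n = 6 each), a log2 difference of 1.16 (adjusted p = 1.13e-06). AT1G62250 rose from 3.54 ± 0.388 to 9.91 ± 0.157 (log2 difference 1.11), and AT3G09080 from 0.968 ± 0.0638 to 2.31 ± 0.249 (2.06). CUTA, a plastid copper-binding protein, rose from 3.06 ± 0.209 to 6.33 ± 0.353 (log2 difference 0.75), and FZL, a dynamin-like protein of thylakoid organization, rose from 2.03 ± 0.168 to 3.13 ± 0.380 (0.75). LpxA, an acyltransferase of the lipid A pathway, rose from 0.935 ± 0.145 to 1.36 ± 0.155 (1.61). The sizes depended on the scaling. As deposited, after median centring and after cyclic loess, LpxA was at 0.55, 2.48 and 0.99. In the same order CUTA was at 1.05, 2.98 and 0.55, and FZL at 0.62, 2.55 and 0.42.

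Single-gene probes lower in all 4 scalings numbered 110, and 98 of them also passed with consecutive samples averaged. They include SECE1, a subunit of the plastid Sec translocase (0.970 ± 0.0928 to 0.168 ± 0.0707, log2 difference -0.88, adjusted p = 0.00175, or 0.00896 with consecutive samples averaged). Another is CRR21, an RNA-editing factor of the plastid NDH complex (0.980 ± 0.159 to 0.154 ± 0.0406, log2 difference -0.95, adjusted p = 0.000766, or 0.0146 with consecutive samples averaged). As deposited SECE1 was at -2.61 and CRR21 at -2.70, and after median centring at -0.69 and -0.77. In unscaled deposited values, 68 untested probes were above 0 on all control arrays and listed at 0 on all recovered arrays, and 0 probes showed the opposite. Recovered arrays held more zeros in all (454.2 ± 82.7 against 157.5 ± 2.95), and the floor is unknown. The imbalance may therefore follow from the shift of whole arrays. Of the 68, 9 name a single gene, the brightest being AT5G50350 (1.01 ± 0.229 in control), AT3G52550 (0.988 ± 0.191) and AT1G32220 (0.622 ± 0.0557). The dimmest was AT1G29040 (0.0412 ± 0.00911). The probes of AT2G25870 disagreed: one had a log2 difference of 0.88 (adjusted p = 0.0457) and the other -0.77 (adjusted p = 0.0407). Neither passed with consecutive samples averaged (adjusted p = 0.167 and 0.155). As deposited both lay below 0 (-0.83 and -2.69).

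Deposited values were lower after recovery for most probes, with median log2 differences of -2.50 in the dimmest 25% of probes and -0.11 in the brightest 25%. One scaling factor for all spots of an array cannot give this gap of 2.39, which ran from 2.04 to 2.67 with a pair left out. Even signal on every control spot as the only difference is argued against by the 1847 probes still called after a constant was added to the recovered arrays. Of these 1155 were higher and 692 lower, against 238 and 1819 as deposited. They can come from any other difference between the groups, one of scaling included. The constant was set to match the medians, so the change of direction was partly built in. Even signal of the size that matches the medians (0.428 to 0.459) would leave no control spot below it, had none lain below 0 before. The 25th percentile of every control array was lower (0.272 to 0.311), and control arrays held 157.5 ± 2.95 zeros. These values argue against even signal of that size. How far a smaller even signal accounts for the lower values stays open. Fewer transcripts in recovered plants and an untested alternative, uneven background or stricter background subtraction on one set of arrays, cannot be told apart. A set of 7 genes chosen for roles in reproduction or meristems had a median deposited log2 difference of -2.06 (from -4.36 to -1.57). That of all probes was -1.58. SAP, DME and LAS were called lower in all 4 scalings, and the others of the set did not pass after quantile normalization. The 7 genes are too few to decide, and the tissue sampled is not given.

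Consecutive samples may share a hybridization or an RNA extract. In the brightest 25% of probes their deviations correlated at 0.494 or more in every pair of both groups, and at 0.0409 or less between other samples of a group. No biological explanation was tested, since no label ties these samples to each other.

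Chance can be excluded for the main counts only if the 12 samples are independent, which the likeness of consecutive samples puts in doubt. Of 100 splits of the 12 samples, the real one included, 1 gave as many calls in all (1653, the highest of the others 0), 1 as many higher (903 against 0), 1 as many lower (750 against 0) and 1 as many in 4 scalings (723 against 0). The large difference between the groups also widens the spread within every other split. For averages of consecutive samples, 1 of 10 splits gave 1261 calls and the highest other 0, and 10 splits are too few for a share under 0.05.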
